A study of Oryza sativa with 4 samples.

How the data were processed

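Gene expression was measured in young rice panicles (Oryza sativa) on 4 Affymetrix rice arrays with a biotin label. Per the labels, 2 genotypes were grown in the field in 2013 and 2014: the wild type ZH11, written WT below, and ago2-1, a line with an antisense construct against OsAGO2. Each genotype had 1 array in each year, so n = 2 arrays per genotype. Nothing in the sources used here says how many plants went into an array, so p-values measure the spread between these arrays. Without a block this includes the difference between the seasons and the shift in scale between the years. That spread is mostly shared over all probe sets (40.3 prior against 2 residual degrees of freedom). With each array centred on its median the prior degrees of freedom were 2.72. One label, the RNA extraction text, names a human brain tissue, which cannot be these panicles. The steps of extraction are therefore taken as not given in the sources used here.

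The deposited values are probe set intensities on a linear scale as the authors deposited them, and the steps before them were not repeated here. RMA is named per the submitters' processing notes, with no version. RMA usually gives log2 values, while the deposited ones run up to 27773 and are linear, so log2 was taken here before any test, with no pseudocount. The median intensity was 29.1 on the WT array and 28.8 on the ago2-1 array of 2013, and 45.3 and 45.2 on those of 2014. Sorted values of the 2 arrays of a year differed by 0.12 log2 at most, whereas the sorted values of 2014 lay a median of 0.65 above those of 2013. The arrays of the years were therefore normalized apart as far as the values show, and a level set across the years holds only after the scaling given beside it. The number of arrays limits the precision.

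All 57194 probe sets were tested; none carried a control name. The platform's annotation ties 22436 of them to 1 gene (17905 genes in all), 95 to several and lists none for 34663, which are unnamed here. Gene symbols were taken from the RefSeq table of assembly ASM3414082v1 through the gene number, which matched all 22436. Only names and the neighbourhood of genes were used from that table.

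Differences between the genotypes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 4 arrays without a block, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The years were compared in the same way with the genotype as a term. Probe sets at least 2-fold apart in the same direction in both years were counted without a test, beside the count after 100 shuffles of the probe sets of 2014. The years stand in the titles and mark a shared season, so they pair the samples. Deviations of the same year from the genotype means correlated with r = 0.77 across probe sets, and 86.9% of the variance lay on the component that separates the years. That share was taken on the deposited scale, so it includes the shift in scale between the years. The fit with year as a block was an alternative, as were quantile, median and cyclic loess scaling, a limit to probe sets with a mean above the median, a trend in or a robust prior variance, leaving out probe sets with an _x_at or _s_at suffix, a threshold of 0.1, a 1.5-fold limit and leaving out each array in turn. Leaving out an array without a block mixes the genotype difference with the change between the years. Tests, named genes and these alternatives were set before the data were examined. Added after the data were seen were quantile scaling together with the block, quantile scaling of the list tests, adjustment over the lists written before alone, and the year comparison without each array and without a genotype term.

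Gene lists were tested with camera at a preset inter-gene correlation of 0.01, on the probe set with the highest mean of each gene, with adjustment over all 35 lists of at least 3 measured genes. An estimated correlation and fry were run beside it. The estimated correlation rests on 2 residual degrees of freedom between the genotypes and 1 between the years. Between the genotypes its residuals also hold the shift between the years that genes share. There it gave every list the same adjusted p, so a list that it does not call is not shown to be unchanged. The 9 tested lists written before the data were examined hold argonautes, hexokinases, other small RNA machinery, tapetum and pollen wall genes, meiosis genes, floral MADS-box genes with DL, KNOX genes, reactive oxygen scavenging enzymes and clock genes. NADPH oxidases, with 1 measured gene, and the targeted gene alone were too few for a test. A gene that the meiosis list reached through the name ZEP1 is a zeaxanthin epoxidase and was left out. Another 22 lists were planned by words in gene descriptions, which the annotation used here does not hold. In their place 28 lists were defined from gene symbols after the annotation was seen, of which 26 had enough measured genes. For these the choice of members is not independent of what the annotation names. Members of the lists written before were also reached by symbol, so genes with no matching name were lost. Of 24 planned tapetum and pollen wall genes 14 were named and 12 measured. Names were found for 11 of 18 meiosis genes and 5 of 10 other small RNA genes.

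The genes named are AGO2 and HXK1, the 10 highest and 10 lowest genes between the genotypes and the 6 highest and 6 lowest between the years, and up to 4 members of a list with the smallest p. The rule ranks by the smaller of both within-year (or within-genotype) log2 differences of the same sign, among probe sets of exactly 1 gene whose higher group mean is at or above the median of all probe sets. Only genes past the threshold are ranked where at least as many pass as are named. Between the genotypes 5 genes passed upward and 4 downward, so genes that did not pass are among those named. Other genes named in the text were chosen after their values were seen.

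The steps were tested on simulated data for the comparison of the genotypes with 57194 probe sets, of which 200 were changed, 50 at each of the log2 sizes 1, 2, 4 and 6. With variances drawn from the fitted prior, the fit without a block recovered 0% at 1 and 2, 82% at 4 and 100% at 6 with 0 false calls, and the blocked fit recovered 6%, 98%, 100% and 100% with 14 false calls. With each probe set's raw residual as its noise, the fit without a block recovered 0%, 0%, 38% and 100% with 1 false call, and the blocked fit none. With each probe set's shrunken variance, the fit without a block recovered 0%, 0%, 94% and 100% with 0 false calls, and the blocked fit 100% at each size with 177 false calls. How many true changes the blocked fit finds therefore rests on the noise assumed. Of 20 simulated lists of 12 genes shifted by 0.5, both fits found 20, and of 80 unshifted lists they called 0. The noise of these simulated genes was drawn independently, so this does not test the preset correlation on genes that vary together.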

Results

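Expression in young panicles was compared between the rice cultivar ZH11 (WT) and ago2-1, a line carrying an antisense construct against OsAGO2, an argonaute protein of the small RNA pathways. The study's authors connect this gene to the hexokinase gene HXK1 and to anther development. Each genotype was measured once in 2013 and once in 2014, which gave 4 arrays of 57194 probe sets and n = 2 per genotype. The arrays of a year resembled each other most, with r = 0.989 across probe sets in 2013 and 0.995 in 2014, while arrays of a genotype correlated between the years with 0.974 for WT and 0.980 for ago2-1. Probe sets are not independent replicates, so these values carry no p.

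The targeted gene was examined first. AGO2 (LOC4336991) was not lower on the arrays labelled ago2-1: its log2 intensity was 9.54 on the WT array and 9.62 on the ago2-1 array of 2013, and 10.53 and 10.98 on those of 2014. The difference of 0.26 had a 95% interval from −1.02 to 1.55 (adjusted p = 1), and from −0.10 to 0.63 with year as a block (adjusted p = 0.64). Its sign turned without the WT array of 2013 (−0.23) and without the ago2-1 array of 2014 (−0.41), both across the shift between the years. Its neighbour AGO3 (LOC4336992) differed by −0.22 in 2013 and −0.47 in 2014 (adjusted p = 1). With year as a block the limma fit gave AGO3 −0.34, with a 95% interval from −0.68 to −0.01 (adjusted p = 0.57). The values thus do not show the lower level that the label names, the part of the gene that the construct covers is not given in the sources used here, and directions below are those of the arrays labelled ago2-1. HXK1 had no probe set of its own by name. Of 7 measured genes with hexokinase names none passed the test, and the one with the smallest p, LOC4326776, differed by 0.58 and 0.22.

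Several large differences between the genotypes recurred in both years, each given for 1 probe set of the gene. LOC4331398 lay at 2.29 on the WT array and 11.23 on the ago2-1 array of 2013, and its probe set rose by 8.82 ± 0.17 log2 (SD of the within-year differences, n = 2, adjusted p = 2.49e-13). The adjusted p here are of the fit without a block. Its SE (0.62 for this probe set) rests mostly on a spread shared over probe sets, which includes the shift in scale between the years. These adjusted p do not measure the SD beside them. With year as a block the adjusted p of this probe set was 0.000172. TIFY5 (JAZ2, LOC4342421), a member of the JAZ family of jasmonate repressors, rose by 5.77 ± 0.18. LOC9268613 rose by 6.03 ± 0.33, LOC4340325 by 5.40 ± 0.69 and LOC4327182 by 3.49 ± 0.33. LOC107279825 fell by 6.08 ± 0.22 (adjusted p = 9.08e-08), LOC4326606 fell by 5.12 ± 0.35 and LOC4334795 fell by 4.41 ± 0.05. DREB1G (LOC4330306), a stress-response transcription factor, fell by 3.30 ± 2.32, with differences of −4.94 in 2013 and −1.66 in 2014 (adjusted p = 0.046). Other probe sets of these genes differed by 8.70 for LOC4331398 and 2.95 for LOC9268613, while those of LOC4340325 (−0.06) and LOC4326606 (−0.05) hardly differed, so for these the change is of the probe set and is not shown for the gene. The lower values in 2013 of LOC4331398 (2.29), LOC9268613 (2.05), TIFY5 (2.45), LOC4327182 (2.61), LOC107279825 (2.27) and LOC4334795 (3.16) were dim, and with no background measure used here the sizes and the order of these differences are not settled.

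In total 29 probe sets passed the threshold, 21 higher and 8 lower on the ago2-1 arrays, of which 10 belong to 9 named genes (5 higher and 4 lower). With year as a block 61 passed, 40 higher and 21 lower, 27 of them shared. Scaling all 4 arrays to a common distribution or median left 1 probe set (1 higher and 0 lower by each of quantile, median and cyclic loess scaling), that of LOC4331398 (adjusted p = 0.018 after quantile scaling). The count was 49 without the ago2-1 array of 2013 and 136 without the WT array of 2014, and the lower calls were 18 without the WT array of 2013 and 13 without the ago2-1 array of 2014. LOC4327182 lost its call without the WT array of 2013 (adjusted p = 0.099) or the ago2-1 array of 2014 (0.066). DREB1G lost it with year as a block (0.39) and without the WT array (1.00) or the ago2-1 array of 2013 (0.083).

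Among the other genes named by rank, which did not pass without a block, several passed with year as a block. PHOT1A (LOC4351240), a blue-light receptor, differed by 2.16 in 2013 and 2.83 in 2014 (adjusted p = 0.35, and 0.032 with the block). LOC4343487 differed by 2.05 and 2.61 (0.65, and 0.029), LOC4340084 by 1.99 and 1.83 (1, and 0.022) and LOC4347756 by 1.63 and 1.79 (1, and 0.029). LOC4335658, with 3.79 and 2.33, passed in neither fit (0.24 and 0.098). On the lower side, LOC4329395 differed by −2.80 and −2.87 (0.093, and 0.0044 with the block), LOC9269982 by −2.55 and −2.12 (0.56, and 0.022), LOC4345187 by −1.83 and −2.09 (1, and 0.025) and LOC4338565 by −1.51 and −1.53 (1, and 0.039). LOC4349148 differed by −4.39 and −1.58 (0.12, and 0.36). Leaving out 1 array without a block adds part of the change between the years to the genotype difference. On the deposited scale LOC4335658 rose from 2013 to 2014 by 2.54, LOC4347756 by 3.17 and LOC4340084 by 2.37. Calls that these genes, LOC4349148 and LOC4329395 gained without single arrays are therefore no support for a genotype difference.

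At least 2-fold differences in the same direction in both years were found for 161 probe sets, 88 higher and 73 lower on the ago2-1 arrays, against 20 with opposed directions. Shuffling the probe sets of 2014 gave means of 1.44 higher, 2.68 lower and 4.65 opposed, with maxima of 5, 9 and 10 in 100 shuffles. A shuffle also breaks any link between the years in how variable a probe set is. The observed 20 opposed lay above its maximum of 10, so it is a low baseline for these counts. All 29 probe sets past the threshold without the block and all 61 with it were among the 161. These sets rest on the same within-year differences, so their overlap is no independent support. At 4-fold there were 32 higher, 11 lower and 2 opposed, and at 8-fold 18, 6 and 0. Across all probe sets the differences of the years correlated with r = 0.35 (Spearman 0.23), and their SD was 0.41 in 2013 and 0.28 in 2014.

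**Figure D1:**
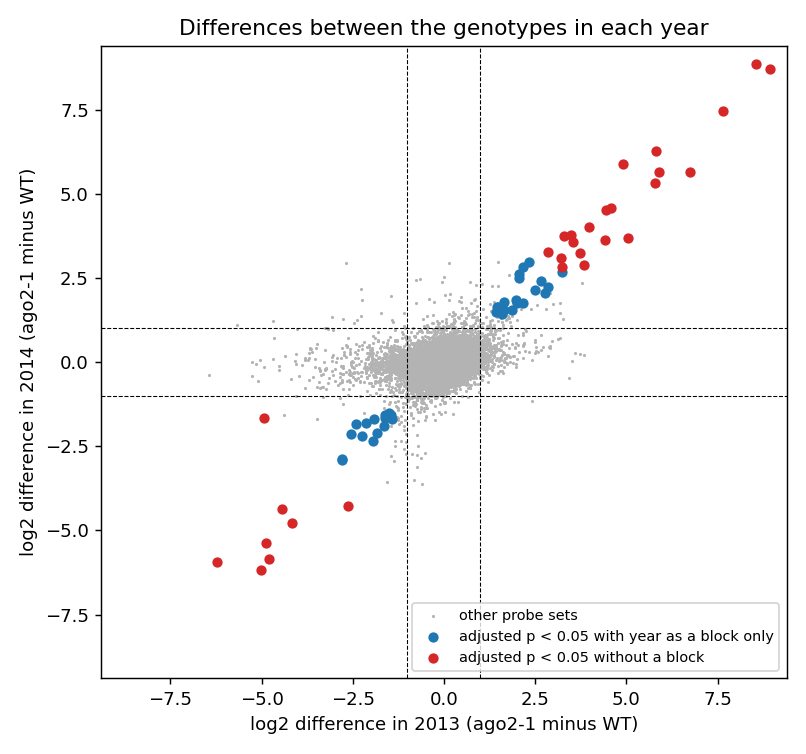
Each point is 1 probe set, with its log2 difference (ago2-1 minus WT) in 2013 on the x axis and in 2014 on the y axis; dashed lines mark 2-fold, and colours mark adjusted p under 0.05 without a block (29 probe sets, red) or only with year as a block (blue). LOC4331398 lies at 8.94 and 8.70 and DREB1G, farther from the diagonal, at −4.94 and −1.66, while grey points spread further along the x axis than along the y axis.

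The list of tapetum and pollen wall genes was called downward on the ago2-1 arrays at the preset correlation (camera adjusted p = 0.000183), but not after quantile scaling (0.079). Nor was it called with an estimated correlation (0.97) or by fry (0.99). After adjustment each of these gave every list the same value, so they hardly separate lists. RAFTIN1 (LOC4345929), a tapetal protein needed for pollen development, differed by −2.14 in 2013 and −1.80 in 2014. CYP703A3 (LOC4344594), a fatty acid hydroxylase of the anther cuticle and pollen exine, differed by −0.86 and −1.65, TDR, a bHLH regulator of tapetum degeneration, by −0.67 and −0.89, and GAMYB (LOC4327362) by −0.31 and −0.43. Of 12 measured members 8 were lower in both years and 1, MSP1, higher, with a median of −0.23. By fry with the block the list had adjusted p = 0.39. No member passed over all probe sets; adjusted over the list alone 1 did, RAFTIN1, which also passed over all probe sets with year as a block (adjusted p = 0.029). The call held with the block (0.0022) and ended without the WT array of 2013 (0.24) and without the ago2-1 array of 2014 (0.77).

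**Figure D2:**
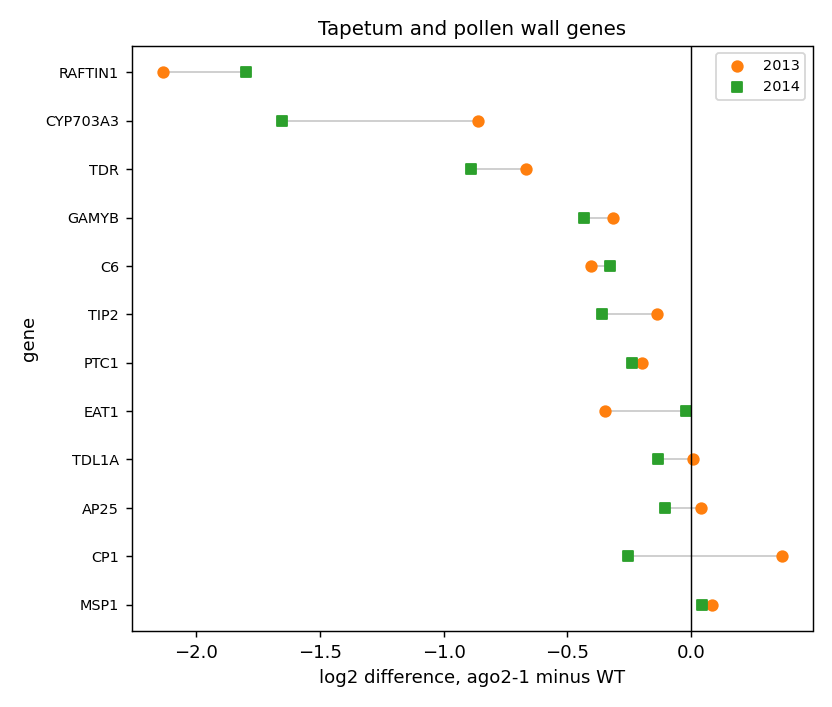
For the 12 measured tapetum and pollen wall genes, the x axis gives the log2 difference (ago2-1 minus WT) in 2013 (circles) and 2014 (squares), 1 array per genotype and year. RAFTIN1 lies lowest, at −2.14 and −1.80, and MSP1 is the 1 gene above 0 in both years.

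Jasmonate genes, a list defined after the annotation was seen, had unlike differences in both years, a contrast that was not tested. TIFY5 rose, by 5.90 in 2013 and 5.64 in 2014, whereas TIFY11E (JAZ13) differed by −5.25 in 2013 and 0.01 in 2014, TIFY11B by −3.67 and 0.40, and TIFY11A by −1.76 and −0.97. The 35 measured members were called downward (adjusted p = 0.032; adjusted p = 0.97 with an estimated correlation), with a median of −0.34 in 2013 and 0.06 in 2014. One member, TIFY5, passed over all probe sets and 2 adjusted over the list alone, TIFY5 upward and TIFY11E downward. The call ended with the block (0.12) and after quantile scaling (0.41). It also ended without the ago2-1 array of 2014 and turned upward without the WT array of 2013. Both of these fits mix the genotype difference with the change between the years.

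**Figure D3:**
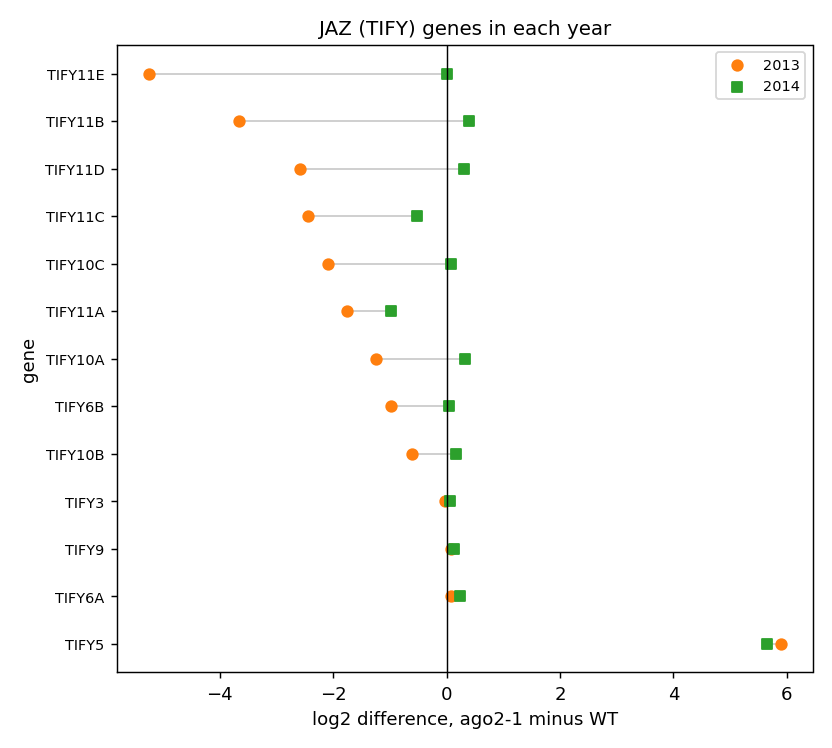
For 13 JAZ genes, by their TIFY names, the x axis gives the log2 difference (ago2-1 minus WT) in 2013 (circles) and 2014 (squares), 1 array per genotype and year. TIFY5 lies at 5.90 and 5.64, and TIFY11E runs from −5.25 in 2013 to 0.01 in 2014.

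Cytochrome P450 genes, also listed by symbol, were lower in both years for 17 of 29 members and higher for 6, with a median of −0.21. ABA8OX1 (LOC9269675), an enzyme of abscisic acid breakdown, differed by −2.80 and −0.13, CYP87A3 by −1.33 and −0.46 and the allene oxide synthase gene AOS1 by −1.22 and −0.12; CYP703A3 is shared with the tapetum list, and no member passed over all probe sets or over the list alone. The list was called downward (adjusted p = 0.020; adjusted p = 0.97 with an estimated correlation), and the call ended with the block (0.088), after quantile scaling (0.083) and without the WT array of 2013 (0.45), the WT array of 2014 (0.055) or the ago2-1 array of 2014 (0.48). By fry, which asks whether the members of a list move one way on balance, the tapetum, jasmonate and P450 lists each had adjusted p = 0.99. In all 3 of 35 lists were called, 1 with the block and 6 without the ago2-1 array of 2013. Calls were gained without single arrays, across the shift between the years. On all 4 arrays with an estimated correlation, the green tissue, WRKY, heat shock and kinesin lists each had adjusted p = 0.97 by camera. Green tissue genes were called downward without the WT array of 2013 (3.77e-06) or the ago2-1 array of 2014 (0.0061) and upward without the ago2-1 array of 2013 (0.027) or the WT array of 2014 (0.023). WRKY factors were called upward without the WT array of 2013 (0.000212) and downward without the ago2-1 array of 2013 (0.021) or the WT array of 2014 (2.25e-05). Heat shock genes were called downward without the WT array of 2013 (2.39e-06) or the ago2-1 array of 2014 (9.77e-07), and kinesins upward without the ago2-1 array of 2013 (0.027).

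The remaining 8 lists written before the data were examined were not called, with adjusted p from 0.37 to 0.88, and none of their members passed over all probe sets or adjusted over the list alone. Argonautes (13 measured, adjusted p = 0.76) had a median of 0.10, with AGO4B at 0.25 and 0.23 and AGO18 at −0.21 and −0.20. Floral MADS-box genes with DL (18 measured, 0.37) were higher in both years for 11 members, MADS14 at 0.56 and 0.24 and MADS18 at 0.57 and 0.23 among them. Clock genes (6 measured, 0.37) had a median of 0.21, with PRR37 at 0.42 and 0.24. Medians were −0.05 for hexokinases (7 measured, 0.78), 0.07 for other small RNA machinery (5 measured, 0.79), 0.02 for meiosis genes (7 measured, 0.88), 0.18 for KNOX genes (5 measured, 0.76) and −0.02 for reactive oxygen scavenging enzymes (11 measured, 0.81). The other 24 lists by symbol had adjusted p of 0.29 or more, though cellulose synthases were called downward among genes above the median level (0.019). Over all genes with an estimated correlation, camera gave cellulose synthases an adjusted p of 0.97. Median and mean differed in sign for 2 lists, protein phosphatases 2C and HD-Zip factors.

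Between the years, the clock genes LHY and PCL1 were among the genes farthest apart in both genotypes. The list of 6 measured clock genes was not called (adjusted p = 0.22, and 0.80 with an estimated correlation), although it was called downward with the mean of all probe sets of a gene (0.043). PCL1 is not among the 6. The list was planned with LUX, which no name in the annotation reached. LUX and PCL1 both lie on chromosome 1, and whether they are the same gene was not checked here. The median change of all genes from 2013 to 2014 was 0.63 log2 on the deposited scale, and changes are given relative to it. LHY (LOC4344703), which peaks at dawn, rose by 6.09, and PCL1 (LOC4326391), an evening gene, fell by 6.02 (adjusted p = 0.000282 for both after quantile scaling). After the same scaling PRR1 fell by 2.98 (adjusted p = 0.0013), GI fell by 3.15 (0.0016) and PRR95 rose by 1.01 (0.0082), while PRR37 (0.14, adjusted p = 0.44) and PRR73 (0.45, 0.071) did not pass. Between the arrays of 2013, LHY differed by 0.07 and PCL1 by 0.30.

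**Figure D4:**
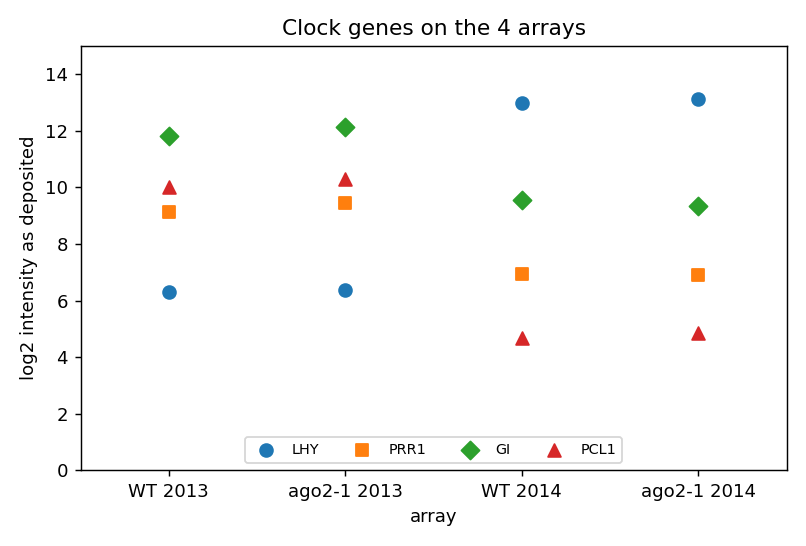
The y axis gives the log2 intensity as deposited of 4 clock genes on the 4 arrays of the x axis, 1 point per gene and array. LHY lies at 6.30 and 6.37 in 2013 and higher in 2014, by 6.68 on the WT arrays and 6.75 on the ago2-1 arrays, while PCL1 moves the other way, by −5.32 and −5.46.

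Other genes that rose from 2013 to 2014 were LOC4326913 by 7.67, LOC4326757 by 7.33, LOC4342551 by 6.44, LOC4335556 by 5.68 and LOC4342135 by 5.18 relative to the median. LOC4328039 fell by 6.72, LOC4343572 fell by 5.82, LOC4349162 fell by 5.74, LOC4334663 fell by 5.32 and LOC4348520 fell by 4.90. After quantile scaling these 10 genes had adjusted p of 0.0013 or less. LOC4326913 (2.42 and 2.43), LOC4326757 (2.24 and 2.28) and LOC4342551 (3.34 and 2.71) were dim on the arrays of 2013. LOC4328039 (3.41 and 3.22) was dim on those of 2014, and LOC4349162 (2.91) and LOC4343572 (3.39) were on the ago2-1 array of 2014. The sizes and the order of such changes are therefore not settled. On the deposited scale 46058 probe sets (80.5%) passed, 44735 higher and 1323 lower. The split was 6995 higher and 6343 lower after quantile scaling (23.3% of all probe sets), 9333 and 5923 after centring on the median, and 6186 and 6665 after cyclic loess. Without a genotype term the count was 23683 without the WT array of 2014 and 23968 without the ago2-1 array of 2014. Year, season and array batch are 1 factor in this design and cannot be told apart.

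Tapetum and pollen wall genes were lower in 2014 relative to the median by 1 test (list median −0.35, adjusted p = 0.00062), but not with an estimated correlation (0.80). PTC1 lay at −1.69 after quantile scaling (adjusted p = 0.0027) and CYP703A3 at −1.93 (0.0068). Jasmonate genes (relative median −0.34, mean −0.73, adjusted p = 5.33e-06) and WRKY factors (−0.93, 0.000397) were called downward, but neither was with an estimated correlation (0.80 for both). The WRKY list holds only 6 measured genes. On the deposited scale 1 of them passed higher and 1 lower, and 2 rose and 1 fell in both genotypes. The relative median of the jasmonate list was −0.61 between the WT arrays and −0.03 between the ago2-1 arrays, and that of the WRKY list −1.66 and −0.31, a contrast that was not tested. With no genotype term both lists were still called without the WT array of 2013 (0.021 for both) and without that of 2014 (0.000179 for jasmonate and 0.00098 for WRKY). Kinesins, motor proteins of dividing cells, were called upward (0.32, adjusted p = 0.033), with 33 of 34 members past the threshold on the deposited scale, where 80.5% of all probe sets passed, and 7 after quantile scaling; the list was not called with an estimated correlation (0.80). Before the shift is taken off, the medians of the tapetum and jasmonate lists were above 0 (0.28 and 0.29) although the test ran downward, and the jasmonate mean was −0.11. Adjusted over the list alone, 7 tapetum genes passed beside 7 over all probe sets, 5 of these higher and 2 lower on the deposited scale, against 0 higher and 5 lower after quantile scaling.

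After quantile scaling 5 lists were called: kinesins (0.0074) and jasmonate genes (0.015) still, with heat shock genes (0.0095) and green tissue genes (0.015) added upward and cellulose synthases (0.015) downward. On the deposited scale with an estimated correlation these 3 had adjusted p of 0.80, 0.81 and 0.80. Among genes above the median level calls were gained downward by expansins (6.24e-09), cytochrome P450 genes (5.37e-05), protein phosphatases 2C (0.0070) and HD-Zip factors (0.044) and upward by green tissue genes (0.044), and with the mean of all probe sets of a gene downward by clock genes (0.043), cellulose synthases (0.024) and cytochrome P450 genes (0.043). No list was called with an estimated correlation on the deposited scale. The calls of the tapetum (0.090) and WRKY (0.099) lists ended after quantile scaling. With no genotype term, calls were also gained by cellulose synthases without the ago2-1 array of 2013 (0.044) or the WT array of 2014 (0.019), cytochrome P450 genes without the ago2-1 array of 2013 (0.015), expansins without the WT array of 2013 (0.024) and green tissue genes without the ago2-1 array of 2014 (0.024). Without the WT array of 2013 or the ago2-1 array of 2014, and with no genotype term, the tapetum list had adjusted p of 0.11 and 0.13. Kinesins lost the call with no genotype term (0.054), among genes above the median level (0.0501), and without the WT array of 2013 (0.12), the ago2-1 array of 2013 (0.063) or the ago2-1 array of 2014 (0.053). The other 8 lists written before the data were examined were not called (adjusted p from 0.22 to 0.92). Members past the threshold on the deposited scale, where most probe sets pass through the shift, with the same count adjusted over the list alone, were 10 of 13 argonautes, 7 of 7 hexokinases, 3 of 5 other small RNA genes, 6 of 7 meiosis genes, 11 of 18 floral MADS-box genes, 5 of 5 KNOX genes, 7 of 11 oxygen scavenging enzymes and 6 of 6 clock genes. After quantile scaling the counts over all probe sets were, in the same order, 3, 1, 3, 3, 2, 0, 3 and 4.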

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

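All tests in this part were chosen after the result was seen, except the cyclic loess test of the JAZ genes and the test of stress-response families, which were set before their values were examined. For 20 probe sets the difference between the genotypes was at least 2-fold in both years with opposed directions, 19 of them lower on the ago2-1 array in 2013 and higher in 2014. The salT gene (LOC4326471) differed by −2.69 and 2.95, WRKY71 (LOC4328512) by −3.06 and 1.32 and DREB1A (LOC4347620) by −1.44 and 1.97. The list medians of 9 green tissue genes (0.11 in 2013 and −0.21 in 2014) and 6 WRKY factors (−0.45 and 0.20) also had opposed signs, each at least 0.1 in size. The difference between the years was not tested in any of these, since a genotype by year term leaves no residual degree of freedom on 4 arrays.

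Genes higher on the WT array of 2013 than on the ago2-1 array of 2013, and not so in 2014, form the first pattern: 181 probe sets were at least 4-fold lower on the ago2-1 array in 2013 and under 2-fold apart in 2014, against 36 in the other direction. LHY and PCL1 differed by at most 0.30 between the 2013 arrays, which argues against a difference in hour of harvest large enough to move these genes. One that leaves them in place stays open. These genes were picked after their values were seen, and the 6 measured clock genes had a median difference of 0.33 in 2013. Genes at the level of each JAZ gene other than TIFY5 had medians from −0.068 to 0.062 in 2013, while the JAZ median was −1.51 (0.11 in 2014). The sorted values of the 2013 arrays already differed by only −0.12 to 0.08, so these medians were bound to lie near 0. They show that no offset by level of the JAZ size is left in the deposited values, and cannot test one before normalization. Cyclic loess left the JAZ median at −1.55 but moved 2013 differences by 0.065 at most, so it was no test of scaling. Stress or wounding of the WT panicles of 2013 could not be decided. The 37 calmodulin-like, DREB and NAC genes, DREB1A and DREB1G left out as already seen, had a median of −0.56 in 2013, below all of 10000 random lists. By family the median was −0.61 for 23 calmodulin-like genes and −1.70 for 8 DREB genes, here with DREB1A and DREB1G, but −0.01 for 8 NAC genes. In 2014 the median of the 37 genes was −0.14, which missed the bound set in advance (above −0.1) and which only 0.05% of random lists reached. A difference not limited to 2013 therefore stays open, as does one between the genotypes, which was not tested.

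The second pattern is the 161 probe sets at least 2-fold apart in the same direction in both years. An exchange of the arrays of 1 year would turn 1 year's directions, and only 20 probe sets were opposed; an exchange in both years would not show in this count, and AGO2, higher on the ago2-1 arrays by 0.08 and 0.45, leaves it open. For a chromosome segment that differs between the lines, 2 pairs of the 71 genes were neighbours, against a median of 0 in 10000 random draws of which 3.07% gave as many, and 1 of the pairs moved in one direction (LOC4340083 and LOC4340084), so that could not be decided. For sequence differences under single probe sets, the bound was a median under 0.5 over other probe sets of the same genes, in the direction of the first. The median over all 21 was 0.40, so the bound was met in the test as first written. Over the 15 with a mean at or above the median, a limit not in that test, it was 0.58 and the bound was not met. This explanation therefore stays open. The other probe set of LOC4331398 followed (8.70), while those of LOC4340325 (−0.06) and LOC4326606 (0.05) did not, and a difference made by the genotype itself stays open and untested.

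The third pattern is the clock genes LHY, PRR1, GI and PCL1 far apart between the years in both genotypes. Scaling between the years is argued against by a gap of 9.06 log2 between LHY and the nearest of PRR1, GI and PCL1 after quantile scaling. Another hour of harvest in 2014 than in 2013 was not decided: 3 of 3 evening genes moved opposite to LHY, but those moves are the pattern itself, and the labels give no hour. Of the other measured clock genes PRR95 rose with LHY (1.01), and PRR37 (0.14) and PRR73 (0.45) did not pass. A difference of season or development between the years was not tested and stays open.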

How the results depend on the processing

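Chosen after the data were seen were the tests with quantile scaling together with the block, quantile scaling of the lists, adjustment over the earlier lists alone, and the year comparison without an array. Named genes kept direction and side of the threshold in 166 of their alternatives, gained a call in 25 and lost one in 14. The causes were not tested, except where fewer probe sets, lists or arrays were used and where prior degrees of freedom were compared.

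Between the genotypes 29 probe sets passed (21 higher, 8 lower). With year as a replicate block 61 passed (40, 21), and 67 (45, 22) with quantile scaling as well; 1 passed (1, 0) after quantile, median or cyclic loess scaling without the block. LOC9268613, for example, differed by 6.03 before and after quantile scaling, but the prior degrees of freedom fell from 40.3 to 2.51; with the block they were 4.36 as deposited and 4.48 after quantile scaling. Probe sets with a mean above the median gave 19 (13 higher), a trend in the prior 51 (20 lower), and leaving out _x_at and _s_at suffixes 13 higher. Leaving out 1 array gave 29 to 136 in all, 16 to 53 higher and 13 to 83 lower. AGO2 reversed to −0.23 without the WT array of 2013 and to −0.41 without the ago2-1 array of 2014, within −0.41 to 0.94 over all arrays left out in turn. A 1.5-fold limit gave 580 probe sets apart in both years (256, 324), and the correlation of the years was 0.45 above the median level. No background measure was used here, so the limit on mean level is the one check of dim probe sets.

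Of the lists, 3 were called between the genotypes, 1 with the block, 0 with an estimated correlation or quantile scaling and 1 adjusted over the earlier lists alone; leaving out 1 array gave 2 to 6. The jasmonate list reversed without the WT array of 2013 (adjusted p = 6.49e-06); over the 4 arrays left out in turn its adjusted p ran from 2.33e-09 to 0.96. Between the years 4 were called, 5 after quantile scaling (3 gained, 2 lost), 7 with the mean of all probe sets of a gene or above the median level, 0 with an estimated correlation and 1 over the earlier lists alone.

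Between the years 46058 passed (44735, 1323), 21859 (21086, 773) above the median level, 15256 (9333, 5923) after centring, 13338 (6995, 6343) after quantile scaling and 12851 (6186, 6665) after cyclic loess. Without an array the genotype term leaves no residual degree of freedom, so it was dropped, which gave 23683 (23280, 403) without the WT array of 2014 and 23968 (23580, 388) without the ago2-1 array of 2014, and 23683 to 41483 in all (23280 to 39868 higher, 388 to 1615 lower). The lists called were 3 to 5. Where an arm kept 1 array, it was assumed to vary like the others. Between the genotypes such fits also took in part of the change between the years. The block changed no call other than those given here and in the results above.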

Other observations

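Genes in this part were chosen after their values were seen. Between 2013 and 2014 several heat shock genes stood far apart in both genotypes. After quantile scaling HSP24.1 (LOC4330786), a small heat shock protein, rose by 4.21 (adjusted p = 0.000482), the heat stress factor HSFA2A (LOC4334080) by 2.77 (0.0015), HSP18.0 (LOC4325342) by 2.03 (0.0023) and the chaperone CLPB3 (LOC4328515) by 1.97 (0.0019), while the factor HSFC1B (LOC4324158) fell by 3.86 (0.000659). These are extremes of a list of 45 measured heat shock proteins and factors, which was not called on the deposited scale (adjusted p = 0.41) or with an estimated correlation (0.80) and was called upward after quantile scaling (0.0095, list median 0.30).

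Some photosynthesis genes, which mark green tissue, also stood apart between the years. After quantile scaling the light-harvesting gene LHCP (LOC4333359) rose by 3.52 (adjusted p = 0.000924), RBCS (LOC4351966), a small subunit of Rubisco, by 2.40 (0.0020) and the photosystem gene PSAH (LOC4339593) by 1.59 (0.0038), while LFNR1 fell by 0.59 (0.028). The list of 9 measured genes was not called on the deposited scale (adjusted p = 0.17) or with an estimated correlation (0.81) and was called upward after quantile scaling (0.015, list median 0.96), among genes above the median level (0.044) and, with no genotype term, without the ago2-1 array of 2014 (0.024). Quantile scaling of the list tests was chosen after the data were seen. The lipoxygenase gene LOX1.1 (LOC4334049) fell by 4.96 (0.000482).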
